A study of Homo sapiens with 66 samples.

How the data were processed

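RNA was measured on 66 Affymetrix HG U133A 2.0 arrays, 1 array per captured sample. Epithelium and stroma had been taken by laser capture microdissection from sections of invasive breast cancer (28 patients) and of reduction mammoplasty tissue (5 patients), which is breast tissue without cancer and is called normal here. Per the labels' protocols, total RNA was extracted without the optional DNase step, amplified with the Ribo-SPIA method and hybridised. The deposited values are on the log2 scale, 1 value per probe set and array. The series design text and the submitters' processing notes name RMA (background correction, quantile normalisation of the probes over arrays and a summary per probe set) as the step that made them. The software version, the chip definition and whether all arrays were processed together are not given in the sources used here. The values ran from 1.27 to 14.43, as log2 RMA values do, and were used as deposited, without a further normalisation.

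Of the 22277 probe sets, 62 were controls and 20113 were in the platform annotation. Of the annotated probe sets, 19064 had a single gene symbol and 1043 had several. A further 2164 were not listed there and stayed unnamed here. Symbols were updated through the gene identifier, which matched for 19052 probe sets and not for 12. Each gene was represented by the single-symbol probe set with the highest mean over the 66 arrays, with no filter on level, which left 11963 genes. Of these, 4310 had several probe sets, and for 853 genes the chosen one carried the suffix that Affymetrix gives to probe sets with probes shared between transcripts. Where several probe sets of a named gene passed the test in opposite directions, that is said. No genome coordinates were used.

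The groups were cancer epithelium (28 arrays), cancer stroma (28), normal epithelium (5) and normal stroma (5), taken from the labels. The 5 comparisons were cancer against normal within epithelium and within stroma, epithelium against stroma within cancer and within normal tissue, and the interaction of diagnosis and cell type, which is the cancer minus normal difference in epithelium minus that in stroma. All were contrasts of 1 linear model with the 4 group means, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of the data.table package. The design text states a model of cell type, diagnosis and their interaction, and says that both compartments came from the patients named there. Arrays with the same diagnosis and number therefore shared a random effect, with a consensus correlation of 0.19 (duplicateCorrelation). The labels do not say that a number marks 1 patient. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 11963 genes. Standard errors are those of the model. Arrays have no count of molecules behind a value, so the number of arrays limits the precision. The median standard error of a log2 change was 0.32 for cancer against normal in either compartment, 0.16 within cancer, 0.38 within normal tissue and 0.41 for the interaction.

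Gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. The 23 lists were fibrillar collagens and matrix proteins, matrix proteases and their regulators, oestrogen-responsive genes, secretory and apocrine breast genes, cell cycle and proliferation, interferon-stimulated genes, immediate-early and stress genes, mesenchymal transition genes, TGF-beta signalling genes, WNT pathway genes, hypoxia and glycolysis genes, oxidative phosphorylation genes, proteasome and protein folding genes, and markers of resident fibroblasts, activated fibroblasts, smooth muscle and pericytes, luminal epithelium, basal and myoepithelial cells, lymphocytes and plasma cells, macrophages and myeloid cells, adipocytes, endothelium and blood cells. No gene was in more than 1 list. Members were matched by current symbol or through an older symbol. Each list was tested in each comparison with cameraPR on the moderated statistics at a preset correlation of 0.01 between genes, and p was adjusted over the 115 tests. The same tests were run with camera and a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Members were also counted with p adjusted over the list alone.

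The named genes were, for each comparison, the 8 called genes with the largest rise and the 8 with the largest fall (5 and 5 within normal tissue and for the interaction). For each list called in a comparison, and for each list of markers of a cell type other than the captured one, up to 4 called members with the largest change were named, or the 2 with the smallest p if none was called. Probe sets with several symbols or none, XIST, Y-linked, immunoglobulin, HLA and haemoglobin genes were left out of naming. Overlaps of calls were compared with the product of the counts over the number of genes. The overlap of the changes with cancer was also set against reassigned diagnoses. These were 100 assignments of the diagnosis over whole patients, the real one included. Correlations over arrays are Pearson r and Spearman rho with permutation p.

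The model was tested on simulated data with known shifts, 5 simulations per comparison. Their unshifted values were deviations from the group means, dealt anew over whole patients of both diagnoses. A simulated normal group therefore held mostly deviations of cancer arrays, unlike the real one. Of genes shifted by 2 on the log2 scale, 80.4% were recovered for cancer against normal epithelium, 79.2% for stroma, 100% within cancer, 72% within normal tissue and 67.2% for the interaction. For shifts of 1 the shares were 49.6%, 49.2%, 87.2%, 41.6% and 35.2%. Beside the shifted genes, 25.4, 74.4, 0, 5.4 and 11.8 unshifted genes were called on average in the same order. The real counts were 177, 34, 5017, 10 and 3, so in stroma and for the interaction the simulations called more unshifted genes than the data had calls. In 20 simulations of the list test the shifted list was called 20 times at the preset correlation and 18 times with an estimated one, and of 440 unshifted lists 98 and 3 were called. The preset correlation therefore called 22.3% of unshifted lists on simulated data, and each list called at it is reported with the estimated correlation beside it.

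Alternatives were the model without the shared effect and with the number as a fixed term, the arrays of the compared groups alone, renewed quantile normalisation, centring on the array median, the mean of all probe sets of a gene, every probe set on its own, array weights, a trended and robust variance, the 3' minus 5' control signal as a covariate, removal of the 33.3% of genes with the lowest mean level, stricter thresholds, 50 draws of 5 cancer patients, and leaving out each normal patient in turn. After seeing the data, 2 were added. These were the 75th percentile of each array as a covariate, and leaving out cancer patients 11, 24 and 28, who hold the arrays closest to each other or farthest from the rest. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Levels of named genes were also compared with the median of each array, likewise after seeing the data. Further details of the patients were not used here.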

Results

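Gene expression was measured on 66 arrays of laser-captured breast tissue. Tumour epithelium and the stroma around it came from 28 patients with invasive breast cancer (28 arrays each), and epithelium and stroma of breast without cancer came from 5 reduction mammoplasty patients (5 arrays each). Values are log2 RMA levels, so a difference of 1 is a 2-fold difference, and 11963 genes were tested. Arrays give no depth, and their number limits the precision. The median level of all probe sets was 2.75 ± 0.06 (SD, n = 28) in cancer epithelium, 2.83 ± 0.06 (n = 28) in cancer stroma, 2.73 ± 0.03 (n = 5) in normal epithelium and 2.80 ± 0.06 (n = 5) in normal stroma. The 75th percentile of the arrays was higher in epithelium than in stroma, at 4.17 ± 0.20 against 3.93 ± 0.17 in cancer and 4.27 ± 0.20 against 3.99 ± 0.18 in normal tissue. The signal of the 3' control probe sets minus that of the 5' ones, a sign of RNA length, was 7.82 and 7.59 in cancer epithelium and stroma and 7.66 and 7.89 in normal epithelium and stroma. The epithelium and stroma arrays of cancer patient 24 correlated at 0.976 over genes, above the highest value for any pair of arrays within a group, 0.951. In the text, values after ± are standard errors of the model unless SD is written, and a gene rose or fell only where its limma adjusted p was under 0.05.

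The first comparison asked how captured epithelium differed between invasive cancer and normal breast. All normal tissue came from reduction mammoplasty. In every comparison of cancer with normal tissue, diagnosis therefore cannot be told apart from the source and handling of the tissue. In cancer epithelium FN1, which encodes fibronectin, and COL1A1, COL1A2 and COL3A1, which encode chains of the fibrillar collagens I and III, rose. Genes of basal and myoepithelial cells, the contractile outer layer of the normal duct, fell, among them the keratin genes KRT14 and KRT15 and the smooth muscle genes ACTG2, MYH11 and TAGLN. Immediate-early genes, which cells switch on within minutes of a stimulus, fell as a group, and so did CXCL2, a chemokine that attracts neutrophils, and KIT, the receptor for stem cell factor. In all, 5 genes rose and 172 fell, and 162 of the 177 changed at least 2-fold.

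FN1 rose 19.6-fold, by 4.29 ± 0.73 on the log2 scale (adjusted p = 5.8e-05, n = 28 and 5), from a mean level of 3.73 to 8.02. All 28 cancer arrays lay above every normal one. COL1A2 rose by 3.20 ± 0.67, COL1A1 by 3.14 ± 0.69 and COL3A1 by 2.01 ± 0.50 (adjusted p = 0.002, 0.0036 and 0.014). BASP1, a membrane-bound protein of nerve endings and other cells, rose by 1.48 ± 0.40 (adjusted p = 0.038), a call kept in 10 of 18 alternatives (adjusted p 0.0015 to 0.26). It was lost with a trended and robust variance (adjusted p = 0.053) and with the 75th percentile as a covariate (adjusted p = 0.064). With the arrays of the compared groups alone BASP1 (adjusted p = 0.085), COL3A1 (adjusted p = 0.078, alternatives 0.00017 to 0.17), ACTG2 (adjusted p = 0.081, alternatives 6.5e-07 to 0.081) and KCNMB1 (adjusted p = 0.098, alternatives 1.1e-05 to 0.27) were not called. Of the 23 measured collagen and matrix genes, 4 rose and 19 did not pass, and 11 rose when adjusted over the list alone. The list was higher in cancer epithelium (mean log2 change 1.46 ± 0.44, adjusted p = 4.99e-13), with adjusted p = 0.0861 with an estimated correlation. Its mean lay above that of normal epithelium in 26 of 28 cancer arrays. Markers of resident fibroblasts, measured beside it, went the other way as a list (mean log2 change -0.41 ± 0.21 over 16 genes, adjusted p = 0.0335, and adjusted p = 0.277 with an estimated correlation). None of them passed singly with limma, with GSN at -1.08 (adjusted p = 0.14) and PDGFRA at -1.53 (adjusted p = 0.36), and 1 fell when adjusted over the list alone.

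CXCL2 fell 46.5-fold (-5.54 ± 0.76, adjusted p = 4.6e-07), from 8.65 to 3.11. KIT fell 22.6-fold (adjusted p = 1e-13) and NTRK2, the receptor for brain-derived neurotrophic factor, 23.7-fold (adjusted p = 3.9e-11). For KIT and NTRK2 all 28 cancer arrays lay below every normal one, and for CXCL2 27 did. Of the named genes that fell, 8 were at or below the median of their array on at least 14 of the 28 cancer arrays, so the size of their falls depends on the low end of the array signal. They were CXCL2 (15), KIT (14), NTRK2 (18), ACTG2 (17), ATF3 (15), CD14 (15), CD8A (24) and KCNMB1 (25), and for CD8A and KCNMB1 the cancer mean itself, 2.54 and 2.28, lay below the mean array median of 2.75. With the mean of all probe sets of a gene, FN1 rose by 2.75 and COL1A1 by 1.41, and NTRK2, SFRP1, MYH11, DUSP1 and GAS1 changed by -1.61, -2.08, -1.36, -1.24 and -1.42, all still called. Over its alternatives NTRK2 ran from -4.78 to -1.61, COL1A1 from 1.41 to 3.26 and FN1 from 2.75 to 4.5. GABRP, a subunit of a receptor for the transmitter GABA, fell by 4.66 ± 0.74 and SFRP1, a secreted antagonist of WNT ligands, by 4.57 ± 0.80. PROM1, a membrane protein of progenitor cells, fell by 4.52 ± 1.0, and SYNM, an intermediate filament protein of muscle, by 4.48 ± 0.79. Of the 19 measured basal and myoepithelial markers 9 fell and 10 did not pass, and 14 fell when adjusted over the list alone. The list mean was -2.02 ± 0.28 (adjusted p = 1.63e-29, and adjusted p = 2.89e-05 with an estimated correlation). KRT15 fell by 4.39 ± 0.64 (adjusted p = 2.4e-06) and KRT14 by 4.47 ± 1.1 (adjusted p = 0.013). For KRT14 1 of the 5 normal arrays lay at 5.29 and the nearest other at 10.3. Of 14 smooth muscle and pericyte markers 4 fell and 10 did not pass, and 10 fell when adjusted over the list alone. The smooth muscle mean was -1.33 ± 0.23 (adjusted p = 4.02e-15, and adjusted p = 0.000123 with an estimated correlation). The 4 were ACTG2 at -3.26 ± 0.73, TAGLN at -2.52 ± 0.58, MYH11 at -2.50 ± 0.40 and KCNMB1, a subunit of a potassium channel, at -0.98 ± 0.23. On the same normal array that lay apart for KRT14, ACTG2 was at 2.79 (nearest other 6.81) and MYH11 at 3.17 (nearest other 5.93).

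Of 24 immediate-early and stress genes 11 fell and 13 did not pass, and 18 fell when adjusted over the list alone. The immediate-early mean was -1.63 ± 0.27 (adjusted p = 1.04e-31, and adjusted p = 0.00011 with an estimated correlation). JUN fell by 3.75 ± 0.64 (13.5-fold, adjusted p = 6.2e-05), FOSB by 3.14 ± 0.61, ATF3 by 2.98 ± 0.47 and the phosphatase DUSP1 by 2.44 ± 0.54. Of 14 secretory and apocrine genes 1 fell, LTF, the milk protein lactoferrin (-4.47 ± 1.1, adjusted p = 0.013), and 2 fell when adjusted over the list alone. The list mean was -0.97 and its median -0.07 (adjusted p = 0.0335, and adjusted p = 0.261 with an estimated correlation).

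No member of 3 further called lists passed singly with limma. Cell cycle genes were higher as a list (mean 0.62 ± 0.28 over 38 genes, adjusted p = 1.4e-08, and adjusted p = 0.177 with an estimated correlation), with UBE2C at 0.80 (adjusted p = 0.33). Interferon-stimulated genes were higher (0.45 ± 0.32 over 27 genes, adjusted p = 0.00203, and adjusted p = 0.467 with an estimated correlation), with IFI27 at 1.49 (adjusted p = 0.52). Oestrogen-responsive genes were higher (0.47 ± 0.47 over 19 genes, adjusted p = 0.0258, and adjusted p = 0.492 with an estimated correlation), with NAT1 at 2.85 (adjusted p = 0.14).

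Among markers of cells that the captured epithelium could also hold, CD14, a receptor of monocytes, fell by 1.91 ± 0.40 (adjusted p = 0.0021) while 20 other macrophage markers did not pass, and 1 fell when adjusted over the list alone (list mean -0.38 ± 0.17, adjusted p = 0.00462, and adjusted p = 0.216 with an estimated correlation). JCHAIN, the joining chain of secreted antibodies, fell by 3.09 ± 0.77 (adjusted p = 0.017), CD8A, a marker of cytotoxic T cells, by 1.46 ± 0.35 (adjusted p = 0.011) and GAS1, from the activated fibroblast list, by 2.72 ± 0.74 (adjusted p = 0.037). The GAS1 call was lost with renewed quantile normalisation (adjusted p = 0.096) and with the 75th percentile as a covariate (adjusted p = 0.063, alternatives 0.00035 to 0.36). The lymphocyte, activated fibroblast, adipocyte, endothelial and blood lists were not called (adjusted p = 0.319, 0.538, 0.502, 0.964 and 0.242), and luminal markers were not either (mean -0.03 ± 0.29 over 23 genes, adjusted p = 0.407). Their examples with the smallest p did not pass, such as KRT7 at -1.48 (adjusted p = 0.21), CFD at -1.67 (adjusted p = 0.41) and ENPP2 at -2.15 (adjusted p = 0.42). Without normal patient 1 (both arrays with that number), 78 genes were called, and array weights raised the count to 706. The calls of BASP1, KRT14, TAGLN, LTF, DUSP1, GAS1, JCHAIN and CD8A were lost without patient 1, of COL3A1, BASP1 and GAS1 without patient 2, of BASP1, KRT14, ACTG2, KCNMB1, LTF, GAS1 and JCHAIN without patient 3, of KRT14, ACTG2, TAGLN, KCNMB1, GAS1 and JCHAIN without patient 4, and of COL3A1, BASP1, KRT14 and LTF without patient 5, with their highest adjusted p between 0.065 (ACTG2) and 0.43 (CD8A).

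**Figure D1:**
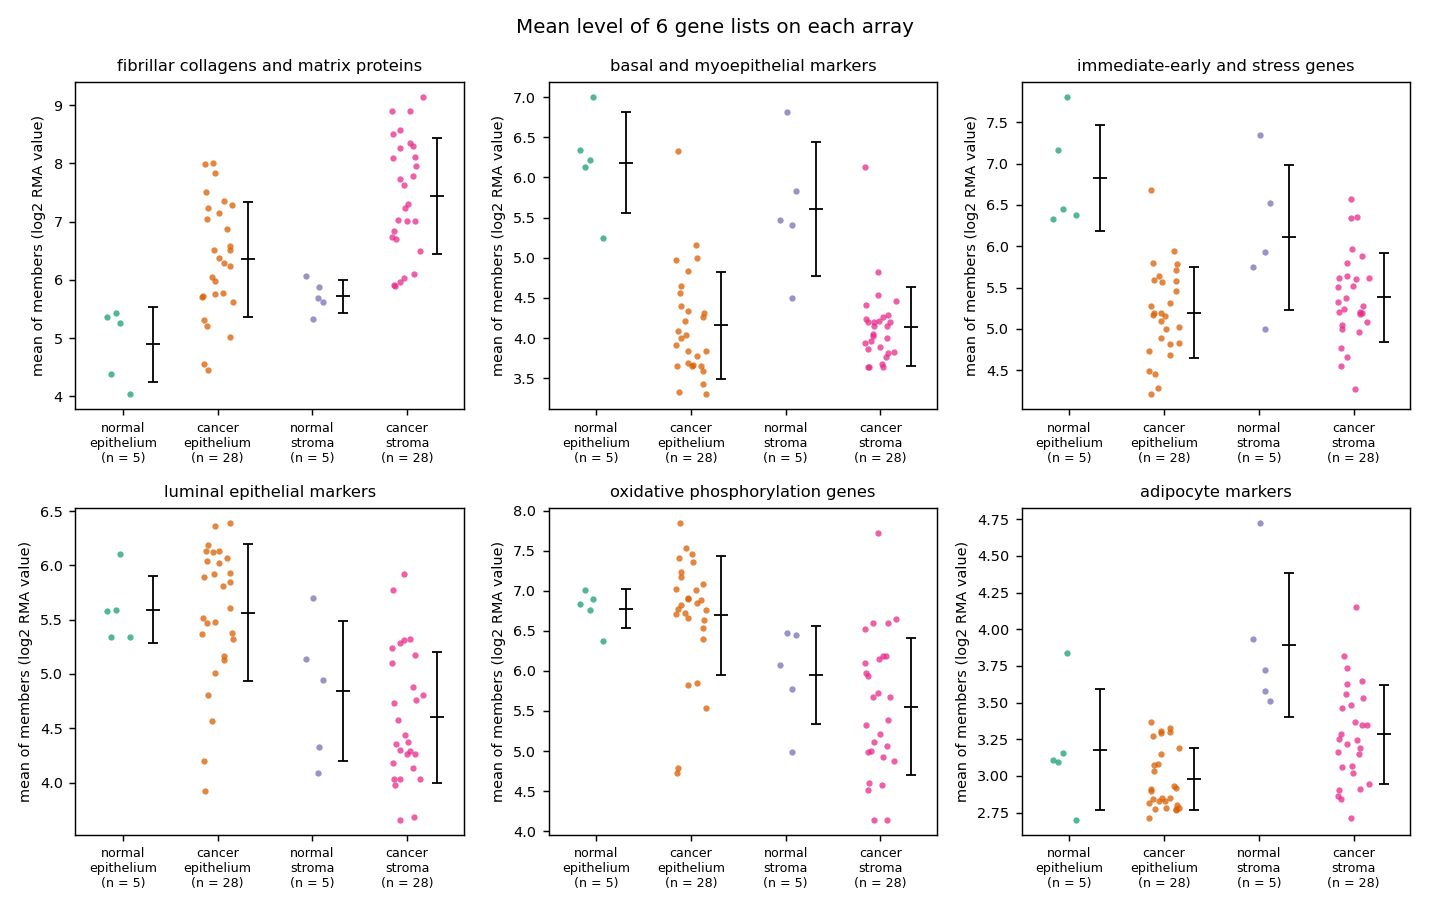
Mean log2 RMA level of the members of 6 gene lists (y axis) on each array, by group (x axis; 28 arrays per cancer group and 5 per normal group); points are arrays, horizontal lines group means and bars 1 SD. Collagen and matrix genes averaged 4.90 in normal and 6.36 in cancer epithelium and 5.72 in normal and 7.45 in cancer stroma, while basal and myoepithelial markers averaged 6.18 in normal and 4.16 in cancer epithelium.

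The second comparison asked the same of the stroma. FN1, COL1A1, COL1A2 and COL3A1 rose in cancer stroma as well, together with POSTN, which encodes the matrix protein periostin. The genes that fell included transcripts of the ductal epithelium, such as KRT15, the transcription factors ELF5, of the milk-secreting lineage, and SOX10, of basal and neural crest cells, GABRP and SFRP1. JCHAIN, made by plasma cells, and JUN fell too. In all, 5 genes rose and 29 fell, each of the 34 by at least 2-fold. When the diagnosis was drawn anew over whole patients, 14 of 100 splits, the real one included, called as many genes. Chance therefore cannot be excluded for this count.

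FN1 rose 15.4-fold, by 3.95 ± 0.73 (adjusted p = 0.0016, n = 28 and 5), and 25 of 28 cancer arrays lay above every normal one. POSTN rose by 3.07 ± 0.72 (adjusted p = 0.031). COL1A2 rose by 2.98 ± 0.67 (adjusted p = 0.017), COL1A1 by 2.97 ± 0.69 (adjusted p = 0.023) and COL3A1 by 2.01 ± 0.50 (adjusted p = 0.0496), a call also lost with median centring and with the 3' minus 5' signal (adjusted p = 0.052 each) and with array weights (adjusted p = 0.21). Of 23 collagen and matrix genes 5 rose and 18 did not pass, and 14 rose when adjusted over the list alone. The collagen and matrix mean was 1.73 ± 0.44 (adjusted p = 2.77e-21, and adjusted p = 0.0293 with an estimated correlation). The list mean was higher than that of normal stroma in 28 of 28 cancer arrays. Matrix proteases and their regulators were higher as a list (mean 0.52 ± 0.16 over 29 genes, adjusted p = 1.72e-05, and adjusted p = 0.0293 with an estimated correlation). No member passed singly with limma, with FAP at 1.14 (adjusted p = 0.18) and MMP1 at 1.87 (adjusted p = 0.30).

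JCHAIN fell 16.1-fold (-4.01 ± 0.77, adjusted p = 0.0025) and lay below every normal array in all 28 cancer arrays. KRT15 fell by 3.75 ± 0.64 (adjusted p = 0.00081), SFRP1 by 4.20 ± 0.80, GABRP by 3.55 ± 0.74 and SOX10 by 3.01 ± 0.60. NTRK2 fell by 2.58 ± 0.46. SOX10 and NTRK2 were at or below the median of their array on 20 and 18 of the 28 cancer arrays, with a mean for SOX10 of 2.65 below the mean array median of 2.83, so the size of these falls depends on the low end of the signal. With the mean of all probe sets of a gene the calls of NTRK2 (-0.33, adjusted p = 0.91, alternatives 8.1e-06 to 0.91), POSTN (1.55, adjusted p = 0.26, alternatives 0.0053 to 0.29) and COL1A1 (1.28, adjusted p = 0.053, alternatives 0.0046 to 0.22) were lost. Those of COL3A1 (2.04, adjusted p = 0.07, alternatives 0.0044 to 0.39), ELF5 (-2.16, adjusted p = 0.053, alternatives 0.018 to 0.13) and MYH11 (-0.61, adjusted p = 0.29, alternatives 0.00029 to 0.29) were lost as well, and FN1, SFRP1, JUN and SOX10 stayed called at 2.48, -1.95, -2.14 and -1.52. ELF5 fell by 4.28 ± 1.0 (adjusted p = 0.031) and PADI2, an enzyme that converts arginine to citrulline in proteins, by 3.34 ± 0.80 (adjusted p = 0.037), a call lost with the 3' minus 5' control signal as a covariate (adjusted p = 0.05, alternatives 0.023 to 0.14). With the arrays of the compared groups alone COL1A1 and ELF5 were not called (adjusted p = 0.07 and 0.052), nor was ELF5 without cancer patients 11, 24 and 28 (adjusted p = 0.053). Of 19 basal and myoepithelial markers 3 fell and 16 did not pass, and 12 fell when adjusted over the list alone. The basal mean was -1.46 ± 0.28 (adjusted p = 1.19e-17, and adjusted p = 0.000856 with an estimated correlation). Luminal markers had a mean of -0.24 ± 0.29 and were not called (adjusted p = 0.0553), with CDH1 at -1.27 (adjusted p = 0.57). MYH11 fell by 1.87 ± 0.40 (adjusted p = 0.01), 13 other smooth muscle and pericyte markers did not pass, and 2 fell when adjusted over the list alone. The smooth muscle list was lower (mean -0.48 ± 0.23, adjusted p = 0.00741, and adjusted p = 0.248 with an estimated correlation). JUN fell by 3.31 ± 0.64 (adjusted p = 0.0025), while 23 other immediate-early genes did not pass and 7 fell when adjusted over the list alone. The immediate-early mean was lower (-0.73 ± 0.27, adjusted p = 1e-07, and adjusted p = 0.0935 with an estimated correlation).

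A further 4 lists were called with no member past the test in limma. Adipocyte markers were lower (mean -0.61 ± 0.15 over 17 genes, adjusted p = 0.00132, and adjusted p = 0.0674 with an estimated correlation), with ACACB, an enzyme of fatty acid metabolism, at -2.18 (adjusted p = 0.052), and 2 fell when adjusted over the list alone. Secretory genes were lower (mean -0.77 ± 0.35 over 14 genes, adjusted p = 0.02, and adjusted p = 0.216 with an estimated correlation), with LTF at -3.36 (adjusted p = 0.21), and 1 fell when adjusted over the list alone. Oxidative phosphorylation genes were lower (mean -0.40 ± 0.36 over 35 genes, adjusted p = 0.015, and adjusted p = 0.597 with an estimated correlation), with COX4I1 at -1.36 (adjusted p = 0.53). With the 75th percentile as a covariate the oxidative phosphorylation mean was -0.21 and the call was lost. Cell cycle genes were higher (mean 0.31 ± 0.28 over 38 genes, adjusted p = 0.00222, and adjusted p = 0.482 with an estimated correlation), with MKI67 at 0.43 (adjusted p = 0.81). Markers of resident and activated fibroblasts, lymphocytes, macrophages, endothelium and blood were not called (adjusted p = 0.314, 0.169, 0.319, 0.314, 0.437 and 0.878). Examples were ABCA8 at -2.52 (adjusted p = 0.093), CXCL12 at -1.84 (adjusted p = 0.058) and ICAM2 at -1.17 (adjusted p = 0.051). Without normal patient 1, 20 genes were called and without patient 2, 85, while renewed quantile normalisation and array weights each gave 53. The calls of POSTN, COL1A2, COL1A1, COL3A1, ELF5, PADI2 and MYH11 were lost without patient 1, of ELF5 without patient 2, of POSTN, COL3A1, ELF5, PADI2 and MYH11 without patient 3, of POSTN, COL1A1, COL3A1, PADI2 and SOX10 without patient 4, and of all of these without patient 5, with their highest adjusted p between 0.082 (SOX10) and 0.39 (COL3A1).

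**Figure D2:**
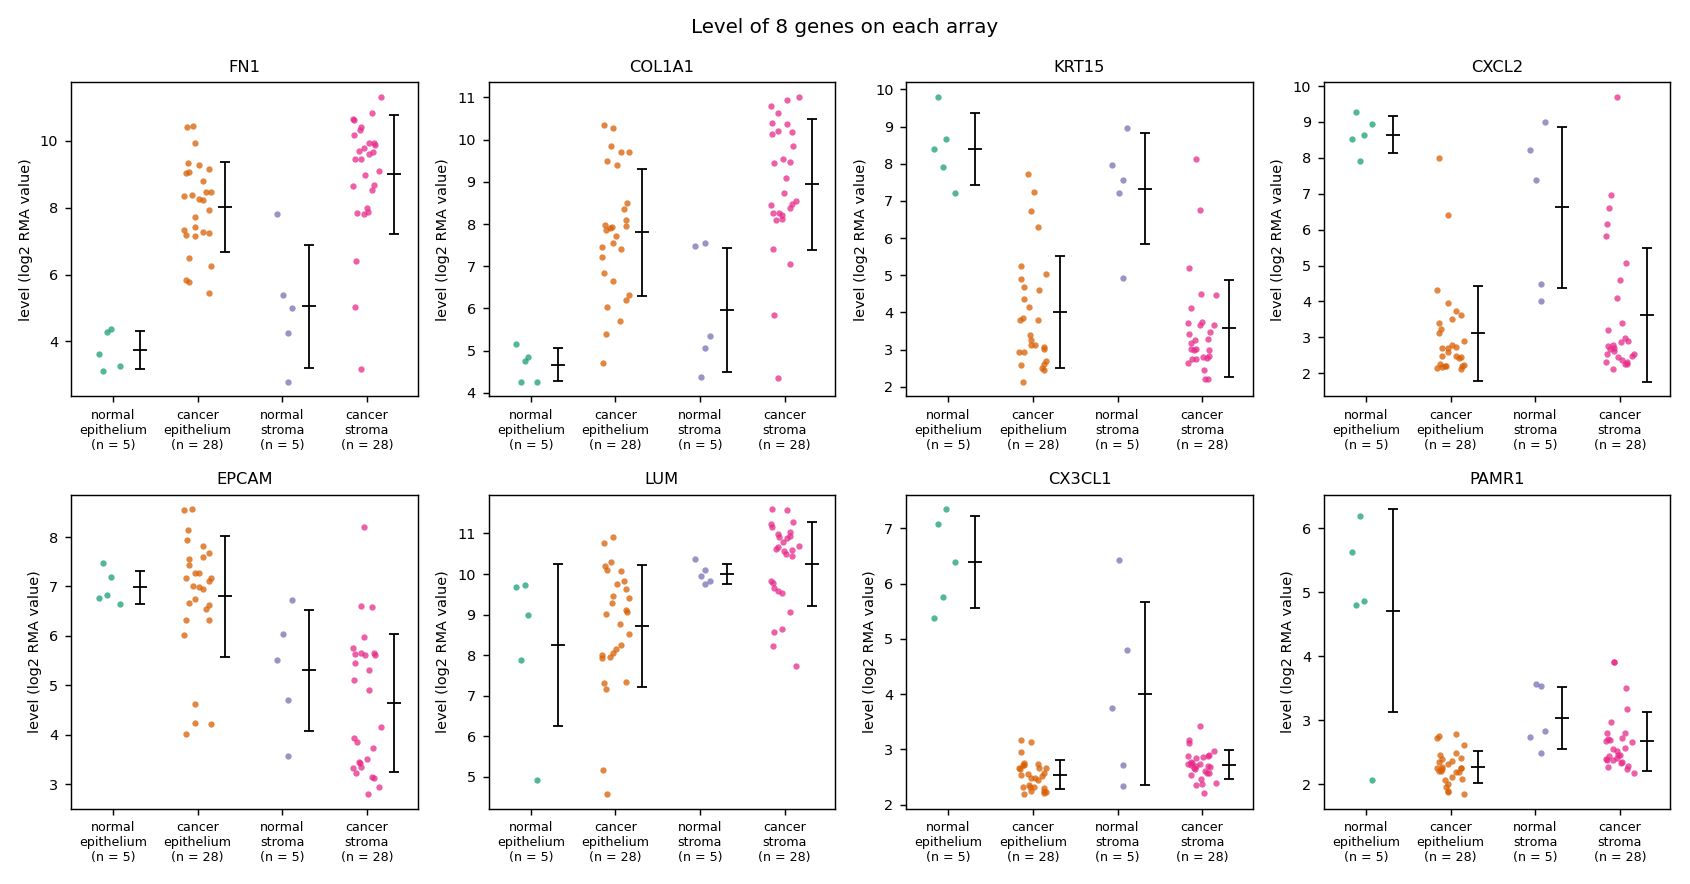
Log2 RMA level (y axis) of 8 genes on each array, by group (x axis; 28 arrays per cancer group and 5 per normal group); points are arrays, horizontal lines group means and bars 1 SD. FN1 averaged 3.73 in normal and 8.02 in cancer epithelium, and CX3CL1 averaged 6.39 in normal epithelium, 4.01 in normal stroma, 2.54 in cancer epithelium and 2.72 in cancer stroma.

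The changes with cancer in epithelium and in stroma had 29 called genes in common, 4 higher and 25 lower, where 0.00209 and 0.417 would be shared by chance. The 4 were FN1, COL1A1, COL1A2 and COL3A1. The 25 included KRT15, GABRP, SFRP1, ELF5, SOX10, NTRK2, MYH11, JUN and JCHAIN. Of the 177 genes called in epithelium 164 had the same sign in stroma, and all 34 called in stroma had the same sign in epithelium. Across genes, which are not independent replicates, the log2 changes correlated at 0.58. Reassigned diagnoses gave 0.273 on average and at most 0.657. The covariance was 0.159 against 0.0513 with reassigned diagnoses, a difference of 0.108.

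**Figure D3:**
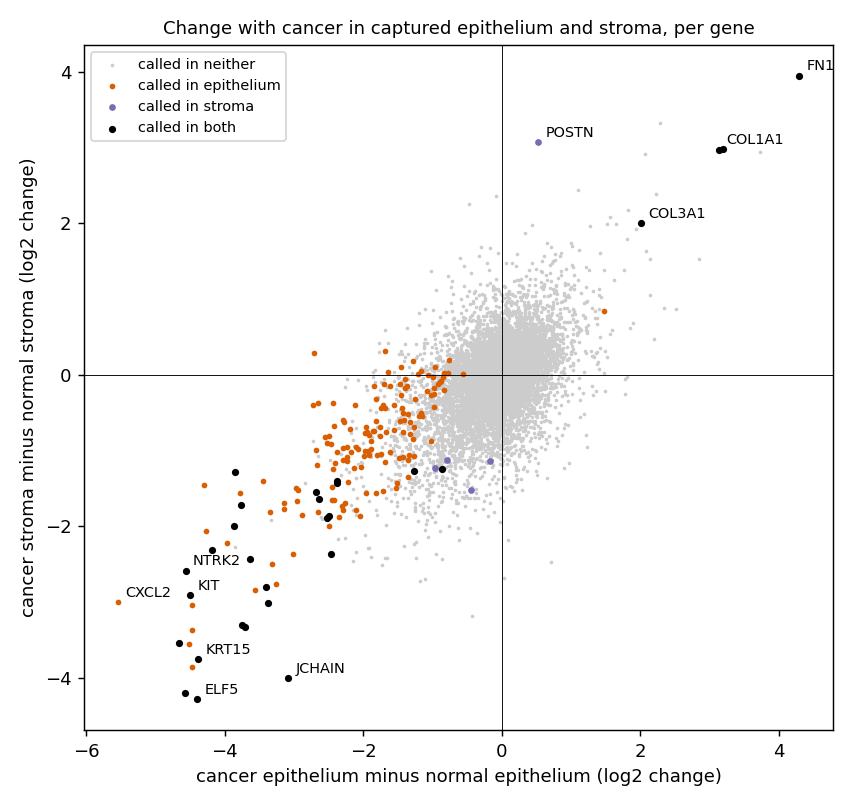
Log2 change with cancer in epithelium (x axis) and in stroma (y axis) for the tested genes. XIST, Y-linked, immunoglobulin, HLA and haemoglobin genes were not drawn. Each point is a gene, coloured by the comparisons in which it was called. FN1 lies at 4.29 and 3.95, KRT15 at -4.39 and -3.75, and POSTN, called in stroma alone, at 3.07 on the y axis.

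The third comparison asked how epithelium and stroma of the tumours differed. Epithelium had higher levels of luminal epithelial genes such as EPCAM, an adhesion molecule of epithelial cells, and KRT19, a keratin of simple epithelia. Mitochondrial respiratory chain genes such as COX7B and NDUFB4 and genes of the proteasome, which degrades proteins, were higher as well. Stroma had higher levels of matrix genes such as LUM (the proteoglycan lumican), THBS2 (a thrombospondin) and COL6A3 (a chain of collagen VI). It also had higher levels of resident fibroblast markers such as FBLN1, IGF1 and PDGFRA. In all, 2291 genes were higher in epithelium and 2726 in stroma, and 943 differed at least 2-fold, 874 of them higher in epithelium and 69 in stroma.

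EPCAM was 4.47-fold higher in epithelium (2.16 ± 0.30, adjusted p = 2.1e-06, n = 28 and 28), at a mean level of 6.81 against 4.65. In 24 of 28 epithelium arrays it lay above the stroma mean. Of 23 luminal markers 13 were higher in epithelium and 10 did not pass, and 14 were higher when adjusted over the list alone. The luminal mean was 0.96 ± 0.14 (adjusted p = 9.75e-09, and adjusted p = 0.0655 with an estimated correlation). AGR2 was higher by 1.85 ± 0.52, KRT19 by 1.84 ± 0.37 and the desmosome protein DSP by 1.72 ± 0.29. Of 19 oestrogen-responsive genes 9 were higher and 10 did not pass, and 10 were higher when adjusted over the list alone. The oestrogen-responsive mean was 0.87 ± 0.23 (adjusted p = 0.00155, and adjusted p = 0.313 with an estimated correlation). The 9 included SLC39A6, a zinc transporter (2.12 ± 0.38), STC2 (1.98 ± 0.67), SERPINA3 (1.80 ± 0.51) and XBP1, a transcription factor of secretory cells (1.53 ± 0.38). Of 38 cell cycle genes 15 were higher, 3 lower and 20 did not pass, and 16 were higher and 3 lower when adjusted over the list alone. The cell cycle mean was 0.46 ± 0.14 (adjusted p = 0.00462, and adjusted p = 0.492 with an estimated correlation). The mitotic kinase AURKA was higher by 1.59 ± 0.45 and NUSAP1, of the mitotic spindle, by 1.58 ± 0.38.

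Of 35 oxidative phosphorylation genes 32 were higher in epithelium and 3 did not pass, and 32 were higher when adjusted over the list alone. The oxidative phosphorylation mean was 1.14 ± 0.18 (adjusted p = 1.51e-16, and adjusted p = 0.0702 with an estimated correlation). COX7B was 5.08-fold higher (2.35 ± 0.38, adjusted p = 1.8e-05), NDUFB4, outside the list, 4.54-fold, and COX8A, COX5B and COX6C were higher by 1.91 ± 0.41, 1.77 ± 0.32 and 1.76 ± 0.39. Of 37 proteasome and protein folding genes 33 were higher and 4 did not pass, and 33 were higher when adjusted over the list alone. The proteasome mean was 1.03 ± 0.18 (adjusted p = 6.28e-14, and adjusted p = 0.115 with an estimated correlation). PSMD14 was higher by 1.97 ± 0.39 and the chaperonin subunit CCT3 by 1.97 ± 0.42. RPN2, of the oligosaccharide transferase of the endoplasmic reticulum, SOD1, which removes superoxide, CNPY2 and EFHD1 were higher by 2.16, 2.12, 2.11 and 2.09. Of 21 hypoxia and glycolysis genes 8 were higher, 1 lower and 12 did not pass, and 9 were higher and 1 lower when adjusted over the list alone. The hypoxia mean was 0.41 ± 0.14 (adjusted p = 0.0269, and adjusted p = 0.44 with an estimated correlation). The glycolytic enzymes ALDOA and TPI1 were higher by 1.38 ± 0.34 and 0.99 ± 0.25. PKM (1.22 ± 0.31) and PSMD4 (2.01 ± 0.38) were higher by the chosen probe set and lower by another. The 75th percentile of the arrays, also higher in epithelium, moved with these lists. With it as a covariate the oxidative phosphorylation, proteasome and hypoxia means were 0.37, 0.28 and -0.14. The luminal, oestrogen-responsive and cell cycle means were then 0.45, 0.58 and 0.11. The hypoxia and cell cycle calls were lost, and of the members of these 6 lists 1 luminal gene was still called in limma.

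Of 23 collagen and matrix genes 20 were lower in epithelium and 3 did not pass, and 22 were lower when adjusted over the list alone. The collagen and matrix mean was -1.09 ± 0.22 (adjusted p = 2.73e-08, and adjusted p = 0.216 with an estimated correlation). LUM was lower by 2.90-fold (-1.53 ± 0.31, adjusted p = 0.00025), THBS2 by 2.82-fold, COL6A3 by 2.68-fold (-1.42 ± 0.24, adjusted p = 4.5e-05) and BGN, the proteoglycan biglycan, by 2.77-fold. CRISPLD2 (-1.59 ± 0.33), AEBP1 (-1.52 ± 0.31), the serine protease HTRA1 (-1.50 ± 0.38) and SPON1 (-1.47 ± 0.33) were lower as well. Of 29 matrix proteases and regulators 13 were lower and 16 did not pass, and 13 were lower when adjusted over the list alone. The protease mean was -0.44 ± 0.08 (adjusted p = 0.00228, and adjusted p = 0.12 with an estimated correlation). Among the proteases were CTSK at -1.40, MMP1 at -1.39, SERPINE2 at -1.22 and MMP2 at -1.17. Of 16 resident fibroblast markers 12 were lower and 4 did not pass, and 13 were lower when adjusted over the list alone. The resident fibroblast mean was -0.76 ± 0.11 (adjusted p = 3.4e-05, and adjusted p = 0.0425 with an estimated correlation). Fibroblast genes among them were FBLN1 at -1.49, PDGFRA at -1.32, IGF1 at -1.25 and MFAP5 at -1.11. Of 17 activated fibroblast markers 9 were lower and 8 did not pass, and 10 were lower when adjusted over the list alone. The activated fibroblast mean was -0.62 ± 0.12 (adjusted p = 0.00213, and adjusted p = 0.149 with an estimated correlation). Activated fibroblast genes among them were TNFAIP6 at -1.30 and LRRC15 at -1.01.

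Of 20 endothelial markers 12 were lower in epithelium and 8 did not pass, and 14 were lower when adjusted over the list alone. The endothelial mean was -0.48 ± 0.08 (adjusted p = 0.00015, and adjusted p = 0.0571 with an estimated correlation). Lower endothelial genes included ENPP2 at -1.20 and ENG at -0.76. Of 21 macrophage markers 9 were lower and 12 did not pass, and 10 were lower when adjusted over the list alone. The macrophage mean was -0.28 ± 0.09 (adjusted p = 0.0144, and adjusted p = 0.277 with an estimated correlation). Lower macrophage genes included ITGAX at -0.71 and MRC1 at -0.65. Of 24 lymphocyte and plasma cell markers 8 were lower and 16 did not pass, and 8 were lower when adjusted over the list alone. The lymphocyte mean was -0.25 ± 0.08 (adjusted p = 0.00664, and adjusted p = 0.277 with an estimated correlation). Lower lymphocyte genes included CD38 at -0.55, MZB1 at -0.46 and IL7R at -0.66. With the 75th percentile as a covariate IL7R was at 0.01. Of 17 adipocyte markers 7 were lower and 10 did not pass, and 7 were lower when adjusted over the list alone. The adipocyte mean was -0.30 ± 0.07 (adjusted p = 0.0311, and adjusted p = 0.239 with an estimated correlation). Lower adipocyte genes included ADH1B, an alcohol dehydrogenase, at -0.61 and CD36 at -0.95. Smooth muscle, mesenchymal transition, blood and basal lists were not called with camera (adjusted p = 0.168, 0.08, 0.13 and 0.867), while fry called the first 3 lower (adjusted p = 0.0252, 0.00542 and 0.00199). Of their genes RGS5 of pericytes (-1.24), CALD1 (-1.03), CAV1 (-0.95) and SLC4A1 (-0.30) were lower and DST of the basal list (1.02) was higher. With the 75th percentile of each array as a covariate, an alternative chosen after seeing the data, 57 genes were called, 9 higher and 48 lower in epithelium. EPCAM and CNPY2 stayed higher, and LUM, THBS2, COL6A3, BGN, CRISPLD2, AEBP1, CTSK, MMP1, PDGFRA, MFAP5, TNFAIP6 and RGS5 stayed lower. Renewed quantile normalisation gave 2855 calls, and centring on the array median gave 3845, with 2596 higher and 1249 lower.

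**Figure D4:**
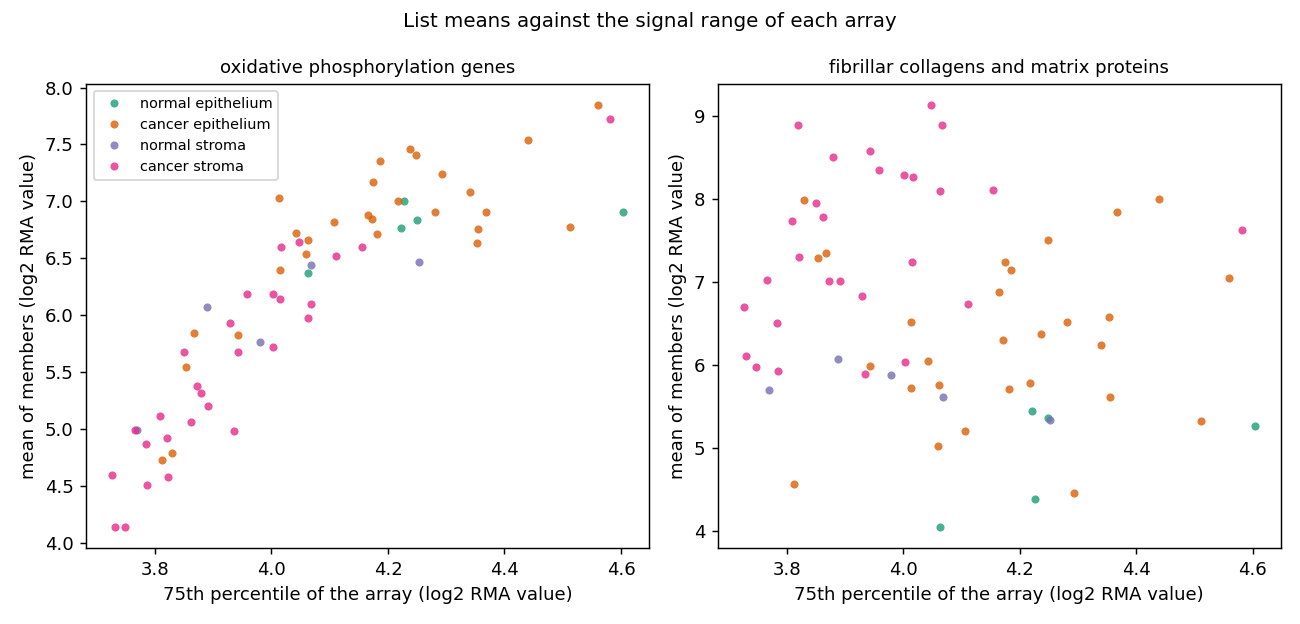
Mean log2 RMA level of the oxidative phosphorylation genes and of the collagen and matrix genes (y axes) against the 75th percentile of each array (x axis, log2 RMA value), for 66 arrays coloured by group. The oxidative phosphorylation mean is higher on arrays with a higher percentile. Collagen levels averaged 7.45 ± 0.99 (SD, n = 28) in cancer stroma and 6.36 ± 0.99 (SD, n = 28) in cancer epithelium, with overlapping ranges.

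The fourth comparison asked the same of normal breast, with 5 arrays against 5. CX3CL1, a chemokine anchored in the membrane of epithelial and endothelial cells, was 5.21-fold higher in normal epithelium than in normal stroma, at a level of 6.39 against 4.01 (2.38 ± 0.29, adjusted p = 2.1e-07). With the normal arrays alone in the model CX3CL1 was not called (adjusted p = 0.14, alternatives 2.8e-12 to 0.14), and of the 6 genes named here only METAP1 was. METAP1, which removes the first methionine from new proteins, was higher by 1.96 ± 0.35 (adjusted p = 0.0019) and PMS1, of DNA mismatch repair, by 2.01 ± 0.43. METAP1 was not called with the 75th percentile as a covariate (adjusted p = 0.072, alternatives 3.1e-06 to 0.11), and of the 6 only CX3CL1 was. With the array number as a fixed term no gene was called within normal tissue. NCOA6, a coactivator of nuclear receptors, was higher by 2.17 ± 0.49 and ROPN1B by 1.91 ± 0.42. CMKLR1, the receptor for the chemoattractant chemerin, was lower by 1.67-fold (-0.74 ± 0.16, adjusted p = 0.04), and lay at or below the array median on all 5 epithelium arrays. In all 9 genes were higher and 1 was lower, and 1831 had an unadjusted p under 0.05. When the normal arrays were split anew into 5 and 5, 6 of 100 splits, the real one included, called as many genes. Chance therefore cannot be excluded for this count.

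For each of these 6 genes all 5 epithelium arrays lay on the named side of the stroma mean. No single member of any list passed with limma, and no list was called with an estimated correlation. Oxidative phosphorylation genes were higher in epithelium (mean 0.83 ± 0.42 over 35 genes, adjusted p = 4.39e-06, and adjusted p = 0.297 with an estimated correlation), as were proteasome genes (0.81 ± 0.42 over 37 genes, adjusted p = 9.53e-06, and adjusted p = 0.359 with an estimated correlation) and luminal markers (0.75 ± 0.34 over 23 genes, adjusted p = 0.000626, and adjusted p = 0.261 with an estimated correlation). With the 75th percentile as a covariate, chosen after seeing the data, these 3 means were -0.11, -0.10 and 0.13. Immediate-early genes (0.72 ± 0.32 over 24 genes, adjusted p = 0.000778, and adjusted p = 0.277 with an estimated correlation), basal markers (0.58 ± 0.32 over 19 genes, adjusted p = 0.0187, and adjusted p = 0.387 with an estimated correlation) and smooth muscle markers (0.54 ± 0.26 over 14 genes, adjusted p = 0.0144, and adjusted p = 0.27 with an estimated correlation) were higher in epithelium too. With the covariate these 3 means were 0.21 each, and the calls of all 6 lists were lost. Collagen and matrix genes were lower in epithelium (-0.82 ± 0.51 over 23 genes, adjusted p = 0.00228, and adjusted p = 0.491 with an estimated correlation), as were adipocyte markers (-0.72 ± 0.17 over 17 genes, adjusted p = 0.000823, and adjusted p = 0.0575 with an estimated correlation) and endothelial markers (-0.49 ± 0.18 over 20 genes, adjusted p = 0.000778, and adjusted p = 0.0832 with an estimated correlation). Resident fibroblast markers (-0.63 ± 0.25 over 16 genes, adjusted p = 0.0311, and adjusted p = 0.277 with an estimated correlation) and blood cell genes (-0.34 ± 0.20 over 5 genes, adjusted p = 0.026, and adjusted p = 0.216 with an estimated correlation) were lower, the blood call being lost with the covariate (mean -0.06). Examples that did not pass were NTRK2 at 1.93 (adjusted p = 0.11), RAB25 at 1.79 (adjusted p = 0.20), ATP5F1A at 1.57 (adjusted p = 0.19), ADIPOQ at -1.98 (adjusted p = 0.17), DPT at -2.65 (adjusted p = 0.11) and COL6A3 at -1.69 (adjusted p = 0.18). Adjusted over the list alone, 4 endothelial, 3 adipocyte, 1 resident fibroblast and 1 blood cell gene were lower, and 1 basal marker was higher.

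Of the 5017 genes called between the tumour compartments, 4635 had the same sign in normal tissue, and of the 10 called in normal tissue 6 had the same sign in cancer. METAP1, NCOA6 and PMS1 were called higher and CMKLR1 lower in both, where 1.72 and 0.228 would be shared by chance, and 1 gene, PAMR1, was called in opposite directions, higher in normal epithelium and lower in cancer epithelium than in the stroma. PAMR1 was at or below the array median on 27 of 28 cancer epithelium and 22 of 28 cancer stroma arrays. For CMKLR1 these counts were 26 and 21. Across genes, which are not independent replicates, the log2 changes correlated at 0.666. In both tissues the change also went with the mean level of a gene. The median change ran from -0.151 at the lowest levels to 0.557 at the highest in cancer, and from -0.185 to 0.569 in normal tissue. Such a shared shift can by itself give shared signs and a positive correlation. How much of either it explains was not tested. Without normal patient 4 the normal comparison called 4 genes, with array weights 523, with the 75th percentile as a covariate 4, after renewed quantile normalisation 3 and with the number as a fixed term 0. The calls of NCOA6, ROPN1B and CMKLR1 were lost without patient 1, of NCOA6, PMS1 and ROPN1B without patient 2, of CMKLR1 without patient 3, of all 4 without patient 4 and of PMS1 and CMKLR1 without patient 5, with their highest adjusted p between 0.16 and 0.27, and 0 of the 6 named calls were kept under every alternative.

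The interaction asked where the change with cancer differed between epithelium and stroma. For CX3CL1, PAMR1 and UAP1L1 the cancer minus normal difference was lower in epithelium than in stroma. These 3 were the called genes, and 506 had an unadjusted p under 0.05 in limma. CX3CL1 averaged 6.39 in normal epithelium, 4.01 in normal stroma, 2.54 in cancer epithelium and 2.72 in cancer stroma. Its interaction was -2.56 ± 0.32 (adjusted p = 2.8e-07). CX3CL1 ran from 5.38 to 7.34 in normal epithelium and from 2.34 to 6.42 in normal stroma. In cancer epithelium it ran from 2.19 to 3.18 and in cancer stroma from 2.21 to 3.42. The model pools the variance of these groups, so the standard error understates the spread of the normal arrays. With the normal arrays alone in limma, the epithelium against stroma difference of CX3CL1 was not called (adjusted p = 0.14). PAMR1, which encodes a secreted protein with a peptidase domain, averaged 4.71, 3.03, 2.27 and 2.67 in the same groups (-2.08 ± 0.33, adjusted p = 0.00017). For PAMR1 1 of the 5 normal epithelium arrays lay at 2.07, below the normal stroma mean of 3.03, and the other 4 lay above that mean. UAP1L1, a relative of an enzyme of amino sugar metabolism, averaged 3.41, 2.36, 2.45 and 2.47 (-1.07 ± 0.18, adjusted p = 0.00061). In both cancer groups the means of CX3CL1, PAMR1 and UAP1L1 lay below the mean array medians of 2.75 and 2.83. Whether the signal there exceeded background was not tested.

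Lists were called without a single member past the test in limma. Immediate-early genes (mean -0.90 ± 0.35 over 24 genes, adjusted p = 5.96e-11, and adjusted p = 0.0425 with an estimated correlation) and smooth muscle and pericyte markers (-0.85 ± 0.29 over 14 genes, adjusted p = 3.22e-07, and adjusted p = 0.0228 with an estimated correlation) had a lower cancer minus normal difference in epithelium than in stroma, with KLF6 at -1.50 (adjusted p = 0.59) and KCNMB1 at -0.72 (adjusted p = 1). The same direction was found for matrix proteases (-0.45 ± 0.20 over 29 genes, adjusted p = 0.00155, and adjusted p = 0.0935 with an estimated correlation), basal markers (-0.57 ± 0.35 over 19 genes, adjusted p = 0.0022, and adjusted p = 0.261 with an estimated correlation), macrophage markers (-0.50 ± 0.22 over 21 genes, adjusted p = 7.38e-05, and adjusted p = 0.079 with an estimated correlation) and mesenchymal transition genes (-0.49 ± 0.30 over 21 genes, adjusted p = 0.00194, and adjusted p = 0.182 with an estimated correlation). Examples were NTRK2 at -1.98 (adjusted p = 0.59), TYROBP at -2.02 (adjusted p = 1) and AXL at -1.22 (adjusted p = 0.70). Adipocyte markers (0.41 ± 0.19 over 17 genes, adjusted p = 0.026, and adjusted p = 0.216 with an estimated correlation) and cell cycle genes (0.32 ± 0.36 over 38 genes, adjusted p = 0.00945, and adjusted p = 0.511 with an estimated correlation) went the other way, the adipocyte call being lost with the 75th percentile as a covariate, with FABP4 at 1.71 (adjusted p = 1) and NUSAP1 at 1.44 (adjusted p = 1). Adjusted over the list alone, 1 immediate-early, 1 basal and 1 mesenchymal transition gene were lower.

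TGF-beta signalling and WNT pathway genes were called as lists in no comparison with camera, while fry called both lower in epithelium within cancer (adjusted p = 0.0063 and 0.000144). Within cancer, 2 of 25 TGF-beta genes were higher and 5 lower in epithelium (mean -0.12 ± 0.07, adjusted p = 0.319), and 5 of 23 WNT genes were lower (-0.16 ± 0.06, adjusted p = 0.181). In cancer against normal epithelium 2 TGF-beta genes and 1 WNT gene fell (list means -0.33 ± 0.13 and -0.33 ± 0.11, adjusted p = 0.202 and 0.197). Of the 115 list tests 52 were called, and 9 of them held with an estimated correlation. Those were the basal, smooth muscle and immediate-early lists in cancer against normal epithelium, the collagen, protease and basal lists in cancer against normal stroma, resident fibroblast markers between the tumour compartments, and the smooth muscle and immediate-early lists for the interaction. With fry 34 were called, 29 of them among the 52. In the called lists the mean, median and test had the same sign. Among lists not called they differed for the luminal, lymphocyte and endothelial markers in cancer against normal epithelium, blood and proteasome genes in stroma, basal markers between the tumour compartments, proteases, cell cycle and TGF-beta genes within normal tissue, and secretory, lymphocyte, TGF-beta and hypoxia genes for the interaction.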

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

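The tests of epithelial transcripts in normal stroma and of a larger share of stroma in cancer epithelium were chosen only after the result was seen, and so were the 75th percentile of each array as a covariate and the comparison of levels with the array medians.

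The first pattern is the 29 genes lower in cancer stroma than in normal stroma, among them transcripts of ductal epithelium such as KRT15 and ELF5. A difference in array signal range is argued against, since with the 75th percentile as a covariate their median log2 change was -2.02 against -1.99 without, and 29 of 29 were still called. A lower share of epithelial transcripts of every kind cannot be decided by comparing basal with luminal markers. Basal markers changed by -1.46 and luminal markers by -0.239 on average, a difference of -1.22 (standard error 0.359). In epithelium the same lists changed by -2.02 and -0.0282, so transcripts carried over from it would give such a difference at any share. The luminal list was not called in stroma. Epithelial transcripts in the captured normal stroma stay open. In 5 of 5 normal patients the median of these genes was higher in epithelium than in stroma, by 0.488 to 1.05. Within normal tissue, however, the median change of all genes between these compartments ran from -0.185 at the lowest levels to 0.569 at the highest. The genes were not set against others of the same level, so their higher median cannot decide this. In epithelium the same genes had a median change of -3.37. JCHAIN, at 10.2 in normal stroma and 8.66 in normal epithelium, is not accounted for by such transcripts. A candidate explanation, not tested further, is that epithelial transcripts reached the captured normal stroma and that basal ones were fewer in that of tumours. A fall within stromal cells was not tested either.

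The second pattern is FN1, COL1A1, COL1A2 and COL3A1, higher in cancer than in normal epithelium. A larger share of stroma in the captured cancer epithelium was tested with the resident fibroblast markers. Their mean change was -0.405 (standard error 0.212) there and -0.271 (standard error 0.212) in stroma. This argues against a larger share of a stroma that keeps these markers. A larger share of a stroma with fewer of them cannot be excluded, since it need not raise them. Activated fibroblast markers changed by 0.0985 in epithelium and 0.299 in stroma on average, and were called in neither. A difference in array signal range is argued against, since with the covariate the median change was 3.26 against 3.17 and 4 of 4 were still called. The same share of a stroma whose own level rose cannot be told apart: over the 28 cancer epithelium arrays the mean of the 4 genes and that of the resident fibroblast markers gave r = 0.35 (permutation p = 0.067), rho = 0.352 (permutation p = 0.066) and r = 0.251 without the 2 farthest arrays. It is kept open by a p above the threshold with r above 0, and a change within the cancer epithelium itself stays open as well, as untested.

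The third pattern is the oxidative phosphorylation and proteasome genes, higher in the epithelium than in the stroma of tumours. RNA quality was tested only as far as the 3' minus 5' control signal carries it. With that signal as a covariate the mean change was 1.03 against 1.08. The signal averaged 7.82 in cancer epithelium and 7.59 in cancer stroma, so as a covariate it could remove little. This argues against a difference in that signal as the source, while other differences in RNA quality were not tested. For a shift shared by all genes of the same level, the members' median of 1.06 was set against 10000 random lists matched on level. It lay at their percentile 100, with a median of 0.488 and a 95th percentile of 0.66. The random lists make no allowance for correlation between members, so this percentile cannot exclude such a shift. With camera and an estimated correlation neither list was called (adjusted p = 0.07 and 0.11). The difference in array signal range cannot be told apart: with the 75th percentile as a covariate the mean change was 0.325 (standard error 0.121) against 1.08 (standard error 0.174) and 0 of 72 members were called in limma. A higher content of these transcripts in epithelial cells, which the design names as a group, stays open and could also raise the percentile.

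The remaining results stood out by an array far from its group or by a difference between compartments. Chance marks about 1 in 20 groups this way, and 6 of 108 groups (5.56%) had an array whose gap to the nearest, over the range of the group, exceeded 0.71. In normal epithelium the gap was 0.933 for KRT14 (5.29, nearest 10.3), 0.739 for ACTG2 (2.79, nearest 6.81), 0.725 for MYH11 (3.17, nearest 5.93) and 0.772 for the mean of the hypoxia list (5.31, nearest 5.96), all on the array of patient 2. It was 0.722 for CD8A in normal epithelium (5.79, nearest 3.86, patient 1) and 0.837 for the mean of the activated fibroblast list in normal stroma (4.36, nearest 4.28, patient 3).

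The interaction test of epithelium and stroma called CX3CL1 (-2.56, adjusted p = 2.8e-07), PAMR1 (-2.08, adjusted p = 0.00017) and UAP1L1 (-1.07, adjusted p = 0.00061). For CX3CL1 the standard error behind this p understates the spread of the normal arrays, since cancer arrays of small spread were pooled with them. Both cancer means of each gene lay below the mean array medians of 2.75 and 2.83, so the data do not separate a differing change with cancer from a difference between the normal compartments alone. The test also called the lists of matrix proteases (-0.448), smooth muscle markers (-0.854), basal markers (-0.565), cell cycle genes (0.318), macrophage markers (-0.503), adipocyte markers (0.414), immediate-early genes (-0.902) and mesenchymal transition genes (-0.494). With an estimated correlation the smooth muscle and immediate-early lists passed (adjusted p = 0.023 and 0.043).

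The number of called genes was counted again for 100 splits of the samples, the real one included. For cancer against normal epithelium 1 split, the real one, gave as many genes as the real 177, and the highest other gave 131. This argues against chance as far as 100 splits can tell. Without normal patient 1, however, the real count was 78, below that highest other. The 29 genes shared between the compartments were reached by 1 split (highest other 5), and the 5017 genes within cancer by 1 (highest other 3381). This argues against chance for these counts to the same degree. The 3 genes of the interaction were reached by 4 splits (highest other 10), which argues against chance by this count. On simulated data, however, 11.8 unshifted genes were called for the interaction on average, which leaves the count of 3 open. For cancer against normal stroma 14 splits gave as many as the real 34, and for normal epithelium against stroma 6 gave as many as the real 10 (highest other 12), so chance cannot be excluded for these counts. The splits within cancer and within normal tissue drew arrays without regard to their numbers. The highest other split of the patients called 299 genes in stroma, several times the real count, where the median of the other splits was 3. What set that split apart was not tested.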

How the results depend on the processing

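The tests with the 75th percentile of each array as a covariate, without cancer patients 11, 24 and 28, and of the lists under median centring, array weights and a trended variance were chosen only after the result was seen. Of 219 values for named genes, called or not, most kept their direction and side of the threshold. Under each normalisation, probe set summary, variance and 3' minus 5' setting 194 to 216 did. Without each normal patient 201 to 208 did, against 153 with the 75th percentile (64 weaker). Of the called values, 16 of 27 in cancer against normal epithelium and 7 of 15 in stroma held without each normal patient in turn. So did 74 of 74 within cancer, 2 of 6 within normal tissue and 3 of 3 for the interaction. Under every alternative run, stricter thresholds included, 16, 6, 15, 0 and 3 of them held. The cause was not tested for any change below, except where fewer patients or a stricter threshold made it.

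Array weights gave 706 calls for cancer against normal epithelium (132 higher, 574 lower), 53 for stroma, 523 within normal tissue (199 higher, 324 lower) and 9 for the interaction. Renewed quantile normalisation gave 53 for stroma, 2855 within cancer, 3 within normal tissue and 0 shared between these last 2, in limma. With the 75th percentile as a covariate 57 were called within cancer (9 higher, 48 lower) and 4 within normal tissue, and with the 3' minus 5' signal 5 for the interaction. An adjusted p under 0.01 left 102, 19, 2688 and 5 genes in the first 4 comparisons and overlaps of 15 and 0, and a 2-fold minimum left 943 within cancer. Every probe set on its own gave 9302, 16 and 6 within cancer, within normal tissue and for the interaction. Without the dimmest genes 6 and 1 were called within normal tissue and for the interaction. That filter moved the median change of all genes to 0.152 within cancer (3459 calls, 2292 higher and 1167 lower) and 0.177 within normal tissue. Centring on the median gave 2596 higher and 1249 lower within cancer, against 2291 and 2726. Of 50 draws of 5 cancer patients the median count was 48, 9.5 and 15 (0 to 1823) in the first 3 comparisons and 0 for the interaction (3 with all patients, 506 at an unadjusted p under 0.05 in limma). Of the 52 list calls 9 held with an estimated correlation, and fry called 34 lists, 29 of them among the 52.

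Without each normal patient in turn the counts ran from 78 (patient 1) to 187 for epithelium, 20 (patient 1) to 85 (patient 2) for stroma, 4926 to 4999 within cancer, 4 (patient 4) to 15 (patient 2) within normal tissue and 4 to 6 (patient 2) for the interaction. The overlaps ran from 13 (patient 1) to 46 (patient 2) and from 1 (patient 4) to 5, and the list calls from 46 to 54. Overlaps of 19 and 16 were found without patients 3 and 5, and 5 genes were called for the interaction without patient 1 and without patient 5. Without cancer patients 11, 24 and 28 the counts were 196, 51, 4535, 8 and 4.

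With the 75th percentile as a covariate these turned direction, among IL7R and the lists called with or without it: between the tumour compartments basal markers (adjusted p = 0.037), hypoxia genes (0.38), interferon genes (1.8e-07) and IL7R (log2 change 0.00769), within normal tissue cell cycle (0.02), oxidative phosphorylation (0.94) and proteasome genes (0.72), and in cancer against normal epithelium oxidative phosphorylation genes (0.039). Means of lists called in neither turned too: luminal in cancer against normal epithelium (-0.0282 to 0.204), proteasome in stroma (-0.0132 to 0.17), blood for the interaction (0.0247 to -0.0239), and within normal tissue protease (0.0047 to -0.221), mesenchymal transition (0.221 to -0.227), TGF-beta (0.0271 to -0.0443) and hypoxia genes (0.383 to -0.281).

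The pairing of arrays by number was checked through their deviations from the group means. In cancer the mean correlation was 0.244 for the same number (-0.22 to 0.867, 22 of 28 over 0.1) and -0.00848 for other numbers, and in normal tissue 0.283 (0.0806 to 0.501, 4 of 5 over 0.1) and -0.0698. With no replicate block 170, 43, 3893, 5 and 3 genes were called in the 5 comparisons and the overlaps were 29 and 0. A fixed replicate block gave 4592 within cancer, 0 within normal tissue (limma, 1831 at an unadjusted p under 0.05 with the random block; CX3CL1 had adjusted p = 0.14) and 7 for the interaction. It was not run for cancer against normal, where a patient lies in 1 diagnosis, and the arrays of the compared groups alone cannot give the interaction. The limit set by signal over background was tested only by removing the dimmest genes.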

Other observations

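The tests in this part were all chosen only after the result was seen. In breast tumours the oestrogen receptor, encoded by ESR1, drives a set of genes in luminal cells, and the levels of ESR1 differ between patients. Over the 28 cancer epithelium arrays ESR1 was related to each of the 18 other measured members of the oestrogen-responsive list, which is 18 relations tested, with p adjusted over them. The closest were GREB1, a cofactor of the receptor (r = 0.75, permutation p = 2e-05, rho = 0.687, permutation p = 6e-05, adjusted p = 0.00024, r = 0.739 without the 2 farthest arrays), CA12, a carbonic anhydrase (r = 0.741, p = 3e-05, rho = 0.691, p = 8e-05, adjusted p = 0.00024, r = 0.753 without the 2 farthest), and NAT1, an acetyltransferase (r = 0.711, p = 4e-05, rho = 0.745, p = 4e-05, adjusted p = 0.00024, r = 0.665 without the 2 farthest). XBP1 (r = 0.688, p = 0.00016, rho = 0.58, p = 0.0016, adjusted p = 0.00072, r = 0.77 without the 2 farthest) and SLC39A6 (r = 0.655, p = 0.00029, rho = 0.686, p = 5e-05, adjusted p = 0.001, r = 0.674 without the 2 farthest) followed.

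The progesterone receptor gene PGR, a classical target, had no relation to ESR1 past the threshold (r = -0.0306, permutation p = 0.88, rho = -0.0624, permutation p = 0.75, adjusted p = 0.88, r = -0.0526 without the 2 farthest arrays), nor had KCNK15 (r = 0.16, p = 0.41, rho = 0.19, p = 0.33, adjusted p = 0.44, r = 0.0417 without the 2 farthest) and IGFBP5 (r = 0.342, p = 0.074, rho = 0.163, p = 0.4, adjusted p = 0.083, r = 0.307 without the 2 farthest). The relations were found although the mean of the list in cancer against normal epithelium rested on no single gene past the test. In stroma Pearson r with ESR1 was 0.323 for GREB1, 0.339 for CA12, 0.573 for NAT1, 0.492 for XBP1 and 0.509 for SLC39A6. The correlations with ESR1 made no allowance for the difference in array signal range. How much of them that difference explains was not tested, nor was whether the receptor drives them. Receptor status by other means was not used here.

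Between epithelium and stroma the change of a gene went with its level. In 4 groups of genes of equal size by mean level, from low to high, the median log2 change within cancer was -0.15, -0.14, 0.12 and 0.56, and within normal tissue -0.18, -0.15, 0.12 and 0.57. Within cancer 19 genes were called higher and 1234 lower in the lowest group, and 1394 higher and 232 lower in the highest. Set against 10000 random lists matched on mean level, the median change of luminal markers within cancer (1.06) lay at percentile 100, that of oestrogen-responsive genes (1.04) at 100 and that of cell cycle genes (0.37) at 99.98. The random lists make no allowance for correlation between members. With camera and an estimated correlation none of the 3 lists was called within cancer (adjusted p = 0.066, 0.31 and 0.49). The cell cycle call was also lost with the 75th percentile as a covariate. Within normal tissue, with 5 arrays against 5, the same 3 lists lay at percentiles 91.9, 90.68 and 27.13. Within cancer the median of the hypoxia and glycolysis genes (0.30) lay at percentile 29.52, below the matched median of 0.40.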
